A study of Mus musculus with 7 samples.

How the data were processed

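RNA was measured on 7 Affymetrix arrays of mouse embryonic fibroblasts. The fibroblasts lacked either the tumour suppressor p53 or both p53 and Dnmt1, the maintenance DNA methyltransferase. Each of the 7 groups held 1 array: untreated, 24 h and 48 h of TSA (trichostatin A, a histone deacetylase inhibitor) for both genotypes, and 2 weeks after TSA removal for the p53-Dnmt1-null cells. Per the labels' protocols, total RNA was purified with TriZol and labelled by the standard Affymetrix procedure. The dose of TSA, and how long the cells of the after-removal array had been exposed to it, are not given in the sources used here.

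The deposited values were linear signal intensities, with 1 value for each of 22690 probe sets on each array. Per the submitters' processing notes the authors used MAS5, which condenses the probes of a probe set into a background-corrected signal. Its version and scaling target are not given in the sources used here. The deposited intensity values had the same 2% trimmed mean on every array, 150.0 after rounding, so the authors had already scaled the arrays. Rescaling them to a common trimmed mean changed no array by more than 0.00077%.

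Probe sets were named through an annotation table of the array. It listed 21084 of them, 20393 with 1 gene symbol and 691 with several, and 1606 probe sets were not listed. Symbols of 20364 probe sets were updated through their Entrez identifiers to a current RefSeq gene table of assembly GRCm38.p6, used for names only. No gene was named from a probe set with several symbols. A gene with several probe sets was represented by the probe set with the highest mean log2 value, and 64 control probe sets were left out of the tests.

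Signals were analysed as log2(signal + 11.4), where the offset was the pooled 25th percentile of all signals. The offset keeps dim probe sets from giving large ratios and understates the change of dim genes, so all fold changes here are on that scale. A feature was kept if its signal exceeded the pooled median of 45.6 on at least 1 of the 7 arrays. This left 9390 features, of which 8298 were named genes and 1092 were unnamed probe sets.

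Because no group had a replicate, comparisons between pairs of arrays were described by a size rule, a difference of at least 2-fold. For the TSA comparisons the difference had to be at least 2-fold in the same direction at both 24 h and 48 h. The number that noise alone would pass was taken from 200 simulations of unchanged arrays. Their noise came from the differences between 24 h and 48 h in bins of 200 features, which include real changes between these times and can overstate the noise. They hold no spread between cultures or over 2 weeks, so they can also understate the noise of the genotype and after-removal comparisons.

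Tests used limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment at 0.05. With no change, 469.5 of the 9390 features would be expected at an unadjusted p under 0.05. The genotypes were compared in an additive model of genotype and time over the 6 arrays at 0, 24 and 48 h, with 2 residual degrees of freedom and a prior of 6.36. Its residual holds the departure from additivity, so a genotype difference that changes with TSA counts as error. TSA, its difference between genotypes and the after-removal array were tested over all 7 arrays with 24 h and 48 h pooled, with 2 residual degrees of freedom and a prior of 5.75. A change between 24 h and 48 h counts as error there, and the lone arrays are assumed to vary like the 24 h and 48 h pairs. TSA averaged over genotypes was an added model with 3 residual degrees of freedom, chosen after the fits per genotype had called nothing. The p-values measure the spread between single arrays, which may be technical or hold real changes with time or TSA, and not the spread between cultures.

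The tests were tested on simulated data of 9390 features, with 200 of them changed in each of 5 runs. The genotype test recovered 20.6% of 2-fold and 88.8% of 4-fold changes, with 5.69% of its calls false. The TSA test recovered 1.00% and 30.8% in p53-null cells and 1.60% and 37.2% in p53-Dnmt1-null cells. Of their calls 7.02% and 4.43% were false. The added TSA test recovered 28.4% and 90.0%, with 5.13% false, and the after-removal test 0% and 1.40%. The number of arrays limits the precision of every value.

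The designs, the size rule, the rule for named genes, the alternatives and 25 gene lists were fixed before the data were examined. The lists covered the targeted genes, imprinted, germline, interferon, antigen presentation, cell cycle, p53 target, extracellular matrix, muscle, neuronal, placental, cholesterol, stress, chromatin, histone and housekeeping genes, genes known to go up or down with histone deacetylase inhibitors, X-inactivation RNAs, and markers of epithelial, macrophage, endothelial, erythroid, adipocyte and liver cells. A list was described by limma calls over all features, by calls adjusted over the list alone, and by the percentile of its median among 10000 random lists of the same size matched on mean expression. A list was called apart below percentile 2.5 or above 97.5. A mesothelial list and a Y-linked list were written after the largest genotype differences had been seen. Named genes were the 10 largest increases and 5 largest decreases under the size rule, up to 4 members of each list with the largest changes, and Dnmt1 and Actb. Trp53 was not analysed here.

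Alternatives were quantile normalization, offsets at the 10th percentile and the median, no filter, a filter at the 75th percentile, the mean over a gene's probe sets, a 3-fold threshold, either TSA time alone, limma without the intensity trend, the genotype test without each time pair, and the genotype test without the time term. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.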

Results

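The series addresses the part that DNA methylation plays in keeping genes silent. Expression was measured in mouse embryonic fibroblasts lacking p53 (p53-null) and in fibroblasts lacking p53 and Dnmt1 (p53-Dnmt1-null). Both were profiled untreated and after 24 h and 48 h of TSA. The p53-Dnmt1-null cells were profiled again 2 weeks after TSA removal. There was 1 array per group, 7 in all, so no comparison between a pair of arrays had a replicate check. Median signals ranged from 41.9 on the after-removal array to 48.8 on the p53-null array at 48 h. Across all probe sets other than controls, before the filter, the untreated arrays of the genotypes correlated at r = 0.909. The p53-null untreated and 24 h arrays correlated at r = 0.972. Probe sets and features are not independent replicates.

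Dnmt1, the targeted gene, was lower in every p53-Dnmt1-null array. Its signal was 695.6, 384.4 and 308.2 in p53-null cells at 0, 24 and 48 h of TSA, and 206.5, 74.0 and 109.5 in p53-Dnmt1-null cells, with 123.2 after TSA removal. The genotype difference was -1.77 ± 0.20 on the log2 scale (SE, limma adjusted p = 0.000323), and another probe set of Dnmt1 gave -2.17. Signal remained in the p53-Dnmt1-null arrays. Where the probes lie relative to the deleted part is not given in the sources used here, so Dnmt1 checks the labels only by its direction.

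The genotypes were set apart by genes of surface epithelia on the p53-Dnmt1-null side and genes of fibroblast matrix on the p53-null side. The keratins Krt8 and Krt18, intermediate filament proteins of simple epithelia, had untreated signals of 2081.3 and 2916.7 in p53-Dnmt1-null cells against 58.3 and 22.6 in p53-null cells. Upk3b, a uroplakin, differed by 7.42 ± 0.25 on the log2 scale (SE, 3 arrays per genotype, limma adjusted p = 8.38e-07), and the basal keratin Krt14 by 7.29 ± 0.19. Penk, the enkephalin precursor, differed by -7.21 ± 0.22 (limma adjusted p = 4.58e-07), and periostin, Postn, by -6.93 ± 0.38. These differences were present in the untreated cells and at both times of TSA. The 18S ribosomal RNA controls, outside the tests, were also higher in p53-Dnmt1-null cells at each of these times, by 2.36 ± 0.56 (SD over 3 times) on the log2 scale at the 3' end and 2.07 ± 0.93 at the 5' end.

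Other genes among the largest increases in p53-Dnmt1-null cells were Podxl, Rpl39l, Myrf, Gpm6a, Wnt4 and Msln, with log2 differences of 7.03, 6.98, 6.82, 5.85, 5.43 and 5.41. Among the decreases were Plpp3, Smoc2 and the Wnt antagonist Dkk2, at -5.83, -5.71 and -5.62. Actb, a scaling control, differed by 0.11 ± 0.07 (limma adjusted p = 0.221).

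Of 19 listed epithelial markers with a probe set 14 passed the filter, which keeps a silent gene only where some array reads it higher. Cldn4, Cldn7, Ehf, Muc1 and Ocln were left out by it. Epcam passed it only through the p53-Dnmt1-null array at 24 h of TSA, with untreated signals of 8.0 and 1.9 in p53-Dnmt1-null and p53-null cells. Of the 14 measured markers, 13 were higher in p53-Dnmt1-null cells by limma, 0 were lower and 1 did not pass. Adjusted over the list alone, 14 were higher. The list's median of 2.83 exceeded all of the matched random lists. Of 41 extracellular matrix genes, 34 were lower, 1 was higher and 6 did not pass, with 36 lower and 2 higher when adjusted over the list alone. The matrix median was -1.60, below all of the matched lists. Thrombospondin Thbs2 differed by -4.54 and the collagens Col6a3 and Col11a1 by -4.36 and -4.10. Decorin, Dcn, was the matrix gene that was higher.

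Some germline genes, many of which are silenced by DNA methylation in somatic cells, were higher in p53-Dnmt1-null cells. Of 37 listed genes with a probe set 8 passed the filter, which keeps a silent gene only where some array reads it higher. Of these 8 measured members, 5 rose and 0 fell in the limma test between genotypes, and 3 did not pass; the counts adjusted over the list alone were the same. Tex19.1 differed by 5.32 ± 0.21, the homeobox gene Rhox5 by 4.22 ± 0.18 and the piRNA pathway gene Piwil2 by 3.43 ± 0.26. Tex101 was called although its untreated signals were 7.4 and 4.1, because it was high in p53-Dnmt1-null cells only with TSA. The list's median was 2.40. The placental list had 4 measured members, with 2 higher and 0 lower, 3 and 0 adjusted over the list alone, and Rhox5 is shared by both lists.

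Imprinted genes, expressed from a single parental allele, went in both directions. Of 18 measured, 3 were higher, 10 were lower and 5 did not pass, with 3 and 11 adjusted over the list alone. The growth factor Igf2 was lower by -3.77, Grb10 by -3.35 and Plagl1 by -3.12, while Peg3 was higher by 3.58. Their median was -0.59, at percentile 0.06 of matched lists. Xist, the RNA that coats the inactive X chromosome, was lower by -2.12 ± 0.23 (limma adjusted p = 0.000249), with untreated signals of 350.1 in p53-null and 114.1 in p53-Dnmt1-null cells. The Y-linked gene Eif2s3y had signals of 0.2, 1.2 and 1.1 in p53-null cells and 26.8, 15.3, 19.9 and 56.6 in p53-Dnmt1-null cells. It was chosen after its values were seen, and all of these signals are dim.

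Antigen presentation genes were mostly higher in p53-Dnmt1-null cells, and among interferon and cell cycle genes more were higher than lower. Of 12 antigen presentation genes, 9 were higher and 1 lower, the same counts as adjusted over the list alone, with the MHC class I gene H2-K1 differing by 1.78 ± 0.24. Of 27 interferon genes, 13 were higher and 6 lower, with 13 and 7 adjusted over the list alone. The chemokine Cxcl10 differed by 2.64 and the immunoproteasome subunit Psmb8, a member of both lists, by 2.37. Of 51 cell cycle genes, 23 were higher, 1 was lower and 27 did not pass, with 25 and 1 adjusted over the list alone. The replication licensing genes Cdc6 and Mcm5 differed by 2.54 and 1.79. Of 14 cholesterol synthesis genes, 9 were higher and 0 lower, with 10 and 0 adjusted over the list alone.

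Several markers of other cell types also differed by genotype, as did 1826 of all 9390 features on the higher side and 1817 on the lower. Of 8 macrophage markers 4 were higher and 0 lower by limma, with 4 and 1 adjusted over the list alone, among them the integrin Itgb2 with an untreated signal of 55.2 against 10.4. Of 5 endothelial markers 3 were higher, the same count as adjusted over the list alone. Of 4 liver genes 2 were higher, with 3 adjusted over the list alone, including Apoe at 3.26. Of 2 erythroid markers 1 was higher, also adjusted over the list alone. Of 17 muscle genes 6 were higher and 5 lower, of 19 neuronal genes 2 and 5, and of 11 adipocyte genes 3 and 3. Adjusted over the list alone these were 6 and 5, 3 and 5, and 3 and 3. Muscle, neuronal, adipocyte and erythroid medians lay inside the range of matched lists, at percentiles 34.9, 64.8, 56.1 and 78.1. Macrophage, endothelial and liver medians lay above it, at percentiles 99.7, 99.0 and 97.6. The troponin Tnni1 was higher by 3.88, and Stmn2, a neuronal tubulin regulator, lower by -3.44.

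Among genes known to go up with histone deacetylase inhibitors, 4 of 22 were higher and 9 lower, with 5 and 10 adjusted over the list alone. Among those known to go down, 5 of 10 were higher and 2 lower, unchanged when adjusted over the list alone. Of 21 p53 targets 4 were higher and 4 lower, and of 27 stress genes 5 and 8, the same as adjusted over the list alone. Of 37 chromatin genes 9 were higher and 3 lower, with 1 and 2 adjusted over the list alone. Uhrf1, which recruits Dnmt1 to replicating DNA, was at 600.1 against 290.6 in untreated cells. Of 7 histone genes 1 was higher and 1 lower, also adjusted over the list alone. Of 18 housekeeping genes 7 were higher and 1 lower, with 8 and 1 adjusted over the list alone. Of the lists in this paragraph, only genes known to go up with such inhibitors had a median outside the range of matched lists. It was -0.27, at percentile 1.37.

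In all, 1826 features were higher and 1817 lower between genotypes by limma at an adjusted p of 0.05, and 842 and 946 of them also differed by at least 2-fold. In the untreated arrays alone 886 features were at least 2-fold higher and 998 lower, against ranges of 170 to 246 and 160 to 243 in simulations of unchanged arrays. At all 3 times 480 features were higher and 561 lower. Without the 48 h pair, limma called 1112 higher and 1134 lower. Each genotype was represented by arrays whose labels name no separate cultures, so a difference between genotypes cannot be told apart from a difference between cultures.

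**Figure D1:**
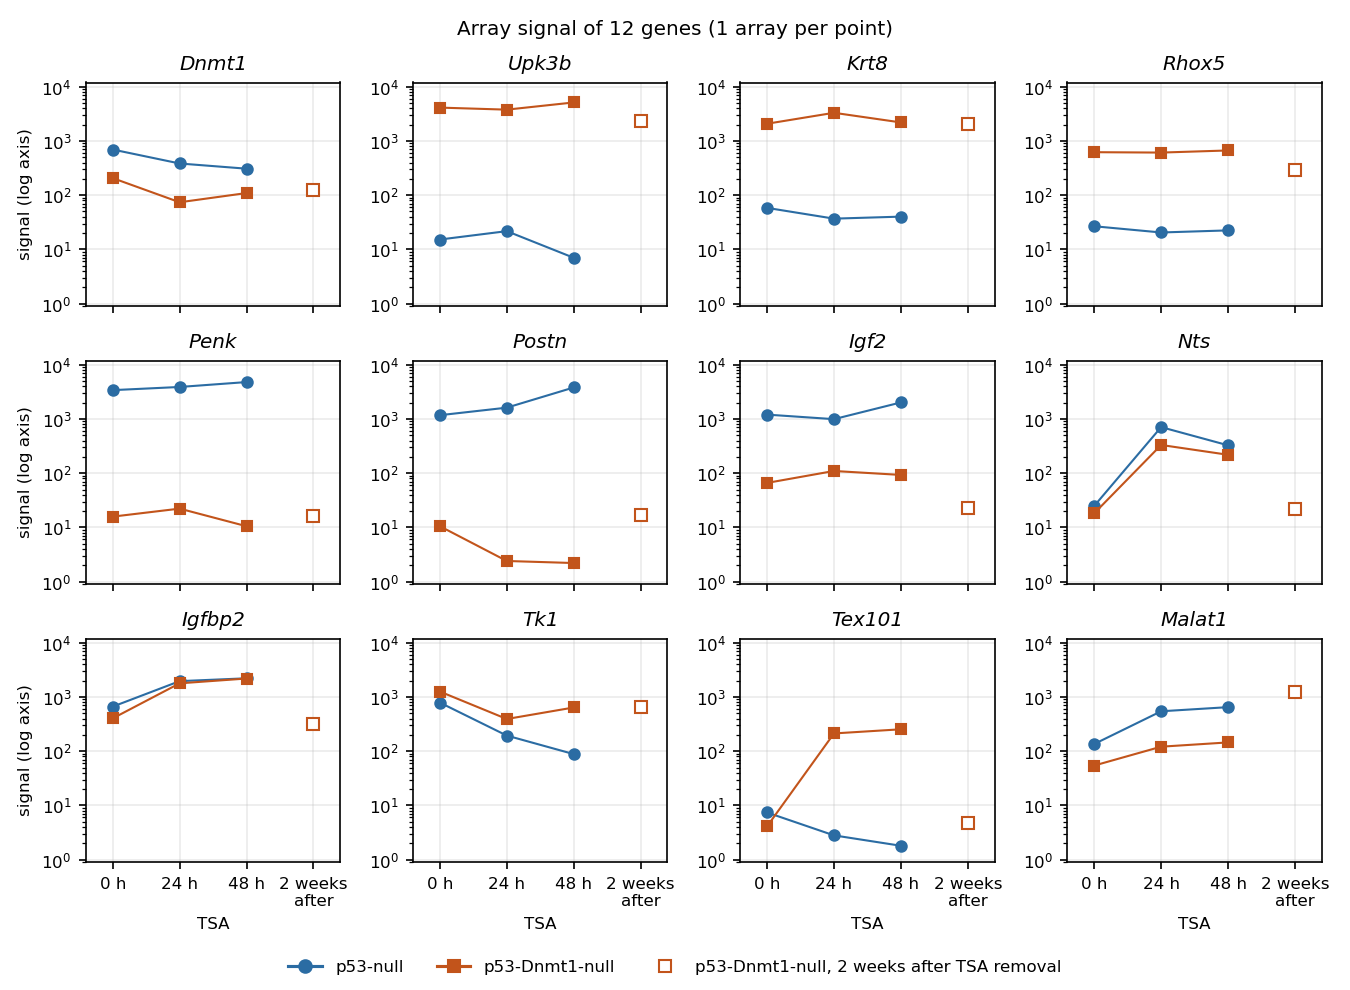
Array signal on a log axis for 12 genes against TSA exposure, with 1 array per point, for p53-null cells (circles), p53-Dnmt1-null cells (filled squares) and p53-Dnmt1-null cells 2 weeks after TSA removal (open squares). Upk3b was 4130.1 in untreated p53-Dnmt1-null cells and 15.2 in p53-null cells, while Nts went from 24.9 to 708.7 within 24 h of TSA in p53-null cells.

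TSA was added to ask which silent genes respond to inhibition of histone deacetylases with and without Dnmt1. In p53-null cells the neuropeptide gene Nts had a signal of 24.9 untreated, 708.7 at 24 h and 327.1 at 48 h. Stmn2 went from 192.7 to 1251.1 and 1092.0, and Qpct, a glutaminyl cyclase, from 11.6 to 160.8 and 147.8. The thymidine kinase Tk1, needed for DNA synthesis, went from 788.6 to 194.3 and 88.5. The connexin Gjb2 went from 285.1 to 48.8 and 21.8.

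Cell cycle genes were lower as a group in p53-null cells with TSA. All 51 measured members had a mean over both times below the untreated value, and their median of -1.10 lay below all of the matched random lists, at -0.72 after 24 h and -1.37 after 48 h. Under the size rule 16 were lower and 0 higher, and by limma 0 were called, with 1 lower when adjusted over the list alone. Plk1, a mitotic kinase, differed by -1.85 ± 0.51 and Mcm5 by -1.76 ± 0.51. Cholesterol genes had a median of -0.45 at percentile 0.07, though -0.15 at percentile 17.3 after 24 h, with 0 called when adjusted over the list alone. Genes known to go down with such inhibitors had a median of -0.66, with 1 lower when adjusted over the list alone.

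Neuronal genes were higher with TSA in p53-null cells, with a median of 0.66 over 19 members. These were the members that passed the filter, of 39 with a probe set. Pcsk1n, Crmp1 and Prph passed it only through TSA arrays, which can raise the median with TSA. The ubiquitin hydrolase Uchl1 differed by 1.97 ± 0.60 and Pcsk1n by 1.95 ± 0.41. Imprinted genes had a median of 0.56 and antigen presentation genes of 0.55, and all of these medians were above percentile 99.9. At 48 h alone the antigen presentation median was 0.24 at percentile 94.2 and the neuronal median 0.38 at percentile 97.4, both inside the range of matched lists. Genes known to go up with such inhibitors had a median of 0.19 at percentile 98.9, with clusterin, Clu, at 1.71 ± 0.32. Matrix genes had a median of 0.13 at percentile 99.6. Adjusted over the list alone, limma called 2 neuronal genes, 1 gene known to go up with such inhibitors, and 0 imprinted, antigen presentation and matrix genes.

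By the size rule 145 features were higher and 94 lower at both times in p53-null cells, against simulated ranges of 29 to 60 and 24 to 61. Limma called 0 features after adjustment, with 799 at an unadjusted p under 0.05 and a lowest adjusted p of 0.241. Among the genes with that p were Nts at 3.77 ± 0.48 and Anxa8 at -2.11 ± 0.33.

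In p53-Dnmt1-null cells several genes with little signal in untreated cells were higher with TSA. Tex101, a germ cell surface protein, had a signal of 4.1 untreated, 212.8 at 24 h and 253.8 at 48 h. Tcn2, which carries vitamin B12, went from 5.7 to 163.7 and 164.4. Crabp2, a retinoic acid binding protein, went from 6.7 to 279.3 and 100.3, and Nts from 18.2 to 331.7 and 218.7. Usp18, an interferon-induced protease, went from 21.4 to 156.4 and 165.4. In untreated p53-null cells Tcn2, Crabp2 and Usp18 were at 103.5, 780.0 and 125.3, so they were not silent in that genotype. Tex101 and Nts were at 7.4 and 24.9 there. Lower signals were seen for Syn3, from 51.0 to 5.1 and 5.8, and for haptoglobin, Hp, from 481.3 to 110.7 and 151.3.

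Neuronal genes were again higher as a group in p53-Dnmt1-null cells, with a median of 0.68. Adjusted over the list alone, 5 of 19 were higher. Peripherin, Prph, was at 695.7 and 157.2 against 31.8 untreated, and passed the filter only through these TSA arrays. Interferon genes had a median of 0.43, with 6 of 27 higher under the size rule and 5 called when adjusted over the list alone, among them Usp18 and Bst2, a tetherin. Muscle genes had a median of 0.48 with 5 called when adjusted over the list alone, including cardiac actin Actc1 at 1.91 ± 0.30 and desmin, Des, at 1.60 ± 0.43. Of 33 muscle genes with a probe set 17 passed the filter, which keeps a silent gene only where some array reads it higher. Medians were 0.46 for epithelial markers, 0.45 for imprinted genes, 0.47 for antigen presentation, 0.44 for genes known to go up with such inhibitors and 0.23 for matrix genes, all above percentile 99.7. At 24 h alone the matrix median was 0.06 at percentile 77.9 and the imprinted median 0.23 at percentile 97.2, inside the range of matched lists, so the matrix call rests on 48 h, at 0.37. Adjusted over the list alone, limma called 0 epithelial, 1 imprinted, 1 antigen presentation and 0 matrix genes, and 3 of those known to go up. Genes known to go down with such inhibitors had a median of 0.09 at percentile 79.3, with 6 of 10 above 0 and 0 called when adjusted over the list alone. Germline genes had a median of 0.04 at percentile 54.2, with 1 called when adjusted over the list alone, Tex101.

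Cell cycle genes were lower in p53-Dnmt1-null cells also, with a median of -0.94 and 49 of 51 members below the untreated value. The median was -1.46 after 24 h and -0.44 after 48 h, and 2 members were lower by the size rule at both times. Lig1, a DNA ligase, differed by -1.59 ± 0.44. Limma called 0 members, also when adjusted over the list alone. Cholesterol genes had a median of -0.30 at percentile 1.53, though -0.02 at percentile 50.2 after 48 h, with 0 called when adjusted over the list alone. The 24 h array of these cells had 18S ribosomal RNA control signals of 2549.1 and 2039.0, above those of every other array.

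By the size rule 176 features were higher and 32 lower at both times in p53-Dnmt1-null cells. The simulated ranges were 43 to 87 and 47 to 82, so fewer features were lower than noise alone gave in the simulations. Limma called 0 features after adjustment, with 736 at an unadjusted p under 0.05. The lowest adjusted p was 0.0836, shared by Igfbp2 at 2.26 ± 0.25, Tex101 at 3.98 ± 0.42, Tcn2 at 3.36 ± 0.39 and Usp18 at 2.39 ± 0.28. With the offset at the median or no intensity trend limma called 1, Tex101, whose adjusted p ranged from 0.0357 to 0.413 over the alternatives. At 24 h alone 565 features were higher and 479 lower, and at 48 h alone 275 and 94.

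Some genes were higher or lower with TSA in both genotypes. By the size rule 25 features were higher in all 4 TSA arrays and 5 were lower, where independent sets would share 2.72 and 0.32, and 0 went opposite ways by that rule. The genotypes share no array in this comparison. The genes included Stmn2, Uchl1, Clu, Ccn3 and Malat1 on the higher side. The lower side held Lig1, Nasp, E2f8, Bcat1 and Syn3, which were named after their values were seen. Across features the TSA response of the genotypes correlated at r = 0.346 at 24 h and 0.384 at 48 h.

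In the added model, TSA averaged over genotypes, 3 genes rose and 0 features fell, and 1406 features had an unadjusted p under 0.05. Nts rose by 3.51 ± 0.33 (limma adjusted p = 0.0141), Igfbp2, an insulin-like growth factor binding protein, by 1.95 ± 0.18 (limma adjusted p = 0.0141) and the ribonuclease Rnase4 by 1.66 ± 0.19 (limma adjusted p = 0.0387). All were higher in 4 of 4 TSA arrays. Without the filter, or without the intensity trend, 0 features passed. The test of the difference in TSA response between genotypes called 0 features by limma. At an unadjusted p under 0.05 there were 291, fewer than the 469.5 expected with no change. The lowest limma adjusted p was 0.761, for Tex101.

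**Figure D2:**
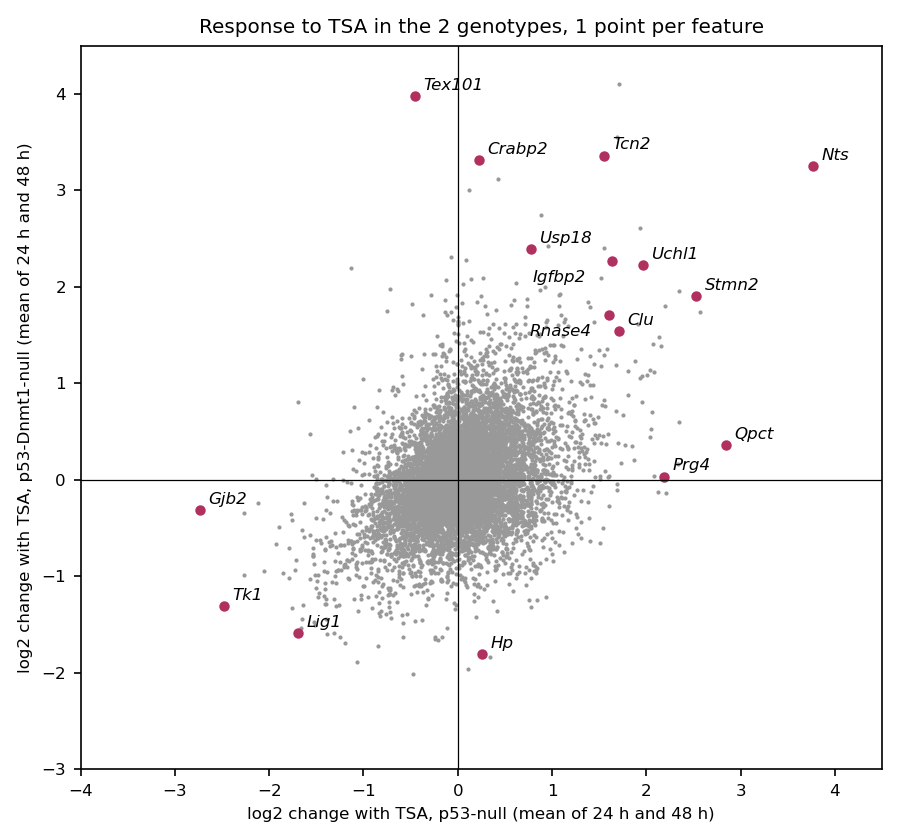
Mean log2 change over 24 h and 48 h of TSA in p53-null cells (horizontal axis) and p53-Dnmt1-null cells (vertical axis), with 1 point per feature and 16 genes named. Nts lies high on both axes, at 3.77 and 3.25, while Tex101 lies high only in p53-Dnmt1-null cells, at -0.46 and 3.98.

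The after-removal array was read for whether the TSA response outlasted the drug. The labels name no untreated array kept for the same 2 weeks, so time in culture is not separated from TSA history. Most genes that were higher with TSA in p53-Dnmt1-null cells were no longer at least 2-fold above their untreated level 2 weeks later. Some were below that level, such as Thy1 at 79.3 against 346.2 untreated. Tex101 returned to 4.8 from 253.8 at 48 h, Nts to 22.3 from 218.7, Usp18 to 16.0 from 165.4 and Igfbp2 to 314.0 from 2194.9. Malat1, a nuclear noncoding RNA, was among the exceptions and stood at 1236.0, against 54.4 untreated and 145.3 at 48 h of TSA. Tcn2 and Crabp2 also stayed at least 2-fold higher, at 29.3 against 5.7 and 26.6 against 6.7 untreated, though these signals are dim.

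Of the 176 features higher at both TSA times, 26 remained at least 2-fold above the untreated array, or 14.8% (95% Wilson interval 10.3 to 20.8). Their median difference from untreated was 0.01, and it had been 1.33 at 48 h of TSA. The median lay at percentile 99.7 of matched lists, whose central range was -0.28 to -0.04, and 4.66% of all features were at least 2-fold higher. In simulations with no lasting change, the shared untreated array alone gave 33.8 to 66.7% among features selected by noise. For the 145 features chosen on the p53-null arrays, which share no array with this comparison, the share was 9.66% (5.84 to 15.6). Only 25 of these 145 met the size rule with TSA in p53-Dnmt1-null cells. Their median change there was 0.44 at 48 h, so this share does not measure how far a response lasted.

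**Figure D3:**
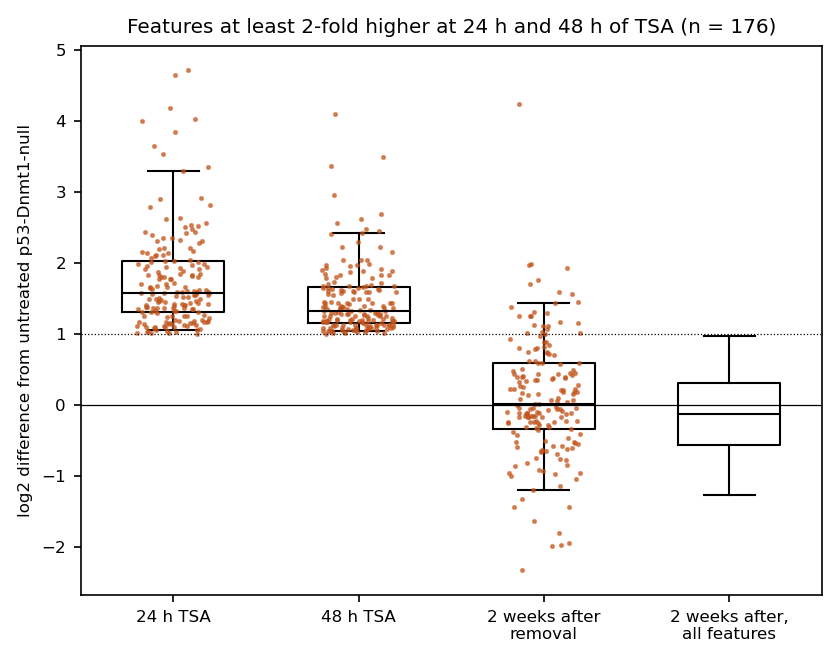
Log2 difference from the untreated p53-Dnmt1-null array for the 176 features at least 2-fold higher at 24 h and 48 h of TSA, and for all 9390 features after removal; boxes show quartiles with the median, whiskers the 5th to 95th percentile, and points single features. The median of the 176 features was 1.33 at 48 h of TSA and 0.01 at 2 weeks after removal.

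Genes of immune signalling and matrix were lower after TSA removal than in the untreated cells. The interferon list had a median of -0.72, with 26 of 27 members below the untreated value and 9 at least 2-fold lower. Ifit1 went from 46.6 to 3.8 and Irf7, an interferon regulatory factor, from 62.2 to 17.9. Antigen presentation genes had a median of -0.78, with all 12 below the untreated value, among them Tap1, the peptide transporter, at 2.0 against 56.7. With the mean over a gene's probe sets that median was -0.25, inside the range of matched lists. Matrix genes had a median of -0.64, with 10 of 41 at least 2-fold lower, among them elastin, Eln, at 29.5 against 235.4 and Col1a2 at 93.9 against 354.6. Limma called 0 members of these lists over all features, and adjusted over the list alone 0 interferon, 2 antigen presentation and 8 matrix genes. Dim signals were lower on this array in general: among the 1878 dimmest features 350 were at least 2-fold lower and 74 higher, and among the 1878 brightest 72 and 51. The bioB spike-in control, the dimmest of its kind, read 85.9 against 187.9 untreated, bioC 239.1 against 334.3, bioD 881.6 against 859.4, and cre, the brightest, 4424.4 against 5555.5. The 18S control at the 3' end read 93.6 against 688.1.

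Genes known to go up with histone deacetylase inhibitors had a median of -0.51 after removal, at percentile 0.27, with 16 of 22 below the untreated value and 0 called when adjusted over the list alone. Endothelial and liver lists had medians of -1.48 and -1.52, both under percentile 0.1, with 2 and 1 members lower when adjusted over the list alone. The keratin Krt7 went from 299.0 to 24.9 and Cldn3, a tight junction protein, from 215.7 to 33.9, and 12 of 14 epithelial markers were below the untreated value. Their median was -0.18 at percentile 45.4, inside the range of matched lists, with 3 lower and 1 higher by the size rule and also when adjusted over the list alone. Krt8 was at 2072.9 against 2081.3. Rhox5 went from 621.3 to 295.0 and Tex19.1 from 757.2 to 152.7, both still above every p53-null array. The imprinted Dlk1 went from 292.8 to 42.8. Cell cycle genes had a median of 0.11 at percentile 98.1, a call lost with the offset at the 10th percentile, and limma called 0 of them, also when adjusted over the list alone. The proliferation marker Mki67 was 679.8 against 309.0.

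In this comparison 905 features were at least 2-fold lower and 438 higher, against simulated ranges of 223 to 303 and 228 to 303. The median of all features was -0.13 lower on the log2 scale, or -0.10 after quantile normalization, and the list values above stand beside that shift. Limma called 1 feature, Malat1, which rose by 4.25 ± 0.35 (limma adjusted p = 0.0254), and 1676 had an unadjusted p under 0.05. Other probe sets of Malat1 gave 3.95, 3.17 and 0.61, another under the filter gave 0.00, and with the mean over probe sets Malat1 was at 2.40. Without the filter, with the mean over probe sets, or without the intensity trend, Malat1 did not pass, and its adjusted p ranged from 0.0165 to 0.195 over the alternatives. Rbfox2 was higher by 2.20, but its other probe sets above the filter gave -0.94 and -0.42.

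**Figure D4:**
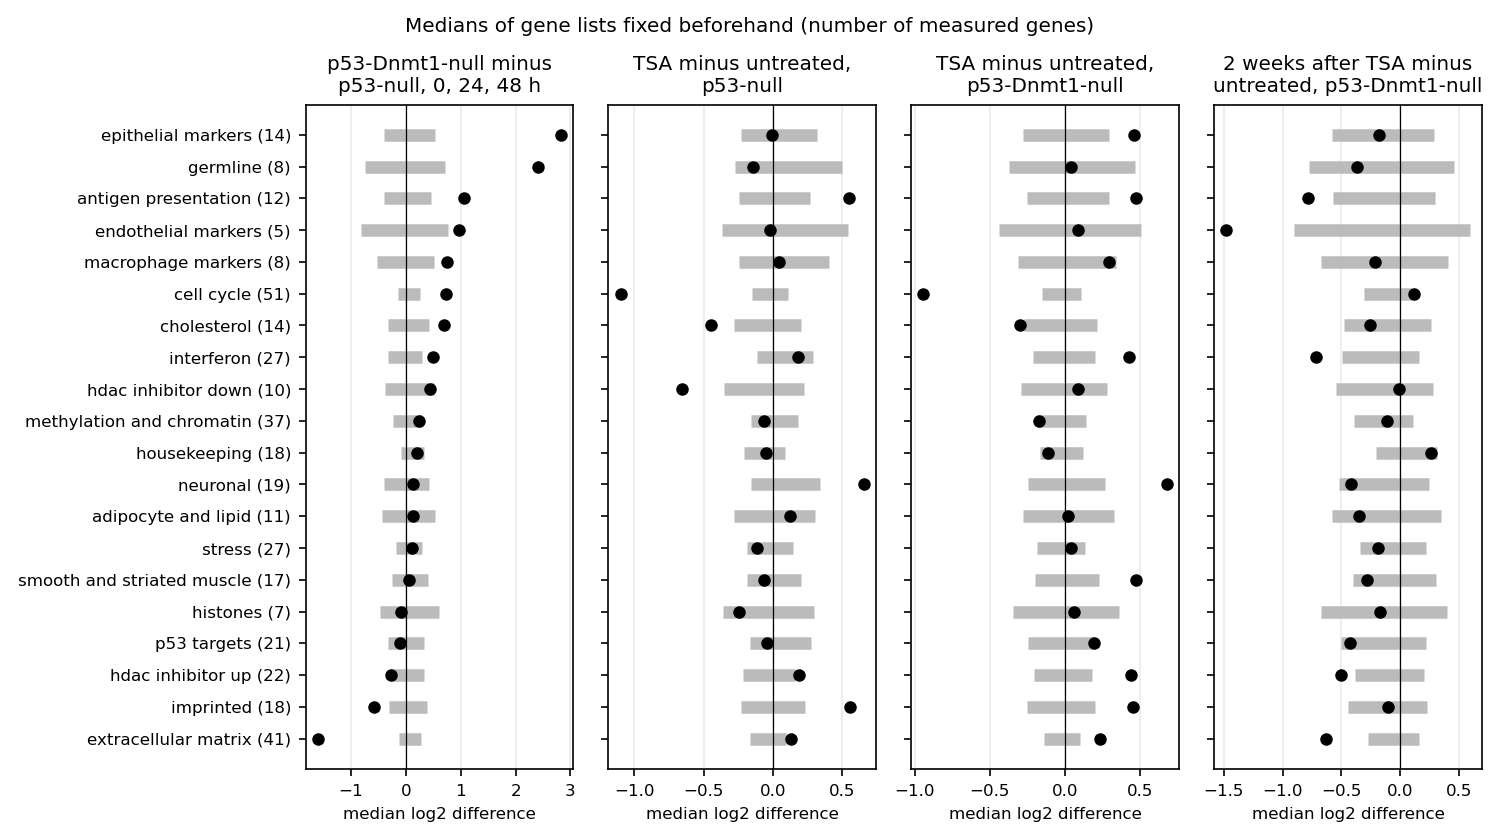
Median log2 difference (points) of gene lists with at least 5 measured genes in 4 comparisons, with the central 95% range of medians of 10000 matched random lists as grey bars and the number of measured genes in brackets. The cell cycle list lies at -1.10 and -0.94 with TSA and the matrix list at -1.60 between genotypes.

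Some genes were higher both in cells without Dnmt1 and with TSA, and others were higher with TSA and lower without Dnmt1. Of the 145 features higher with TSA in p53-null cells, 41 were also at least 2-fold higher in untreated p53-Dnmt1-null cells, where independent sets would share 13.7, and 27 were at least 2-fold lower there. Of the 94 features lower with TSA, 5 were also lower there, where independent sets would share 9.99. Both comparisons use the untreated p53-null array, whose noise enters both. In simulations of unchanged arrays that noise alone gave an overlap of 13 to 43 on the higher side, from smaller sets of 44.0 and 207 features on average, so the 41 cannot be read as an excess over 13.7. Without a shared array the sets were larger. They held 1170 features higher by genotype at 48 h and 317 higher with TSA at 24 h alone in p53-null cells. Of these, 85 were higher in both, where independent sets would share 39.5. As many as 86 were higher with TSA and among the 1156 lower by genotype at 48 h. The overlap was therefore not particular to features higher in both. With the same arrays 22 were lower in both, where independent sets would share 21.4, and 82 were lower with TSA and higher in p53-Dnmt1-null cells. Shares of independent sets were not computed for opposite directions. Both 48 h arrays were under TSA, so a stronger TSA response in p53-null cells itself adds to the opposite directions. Clu was among the genes higher in both, at 125.0 in p53-null cells against 521.0 in p53-Dnmt1-null cells and 529.1 after 48 h of TSA.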

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

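All tests in this part were chosen after the result was seen, except the comparison of the 24 h to 48 h change between genotypes.

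Some control probe sets outside the comparisons read above the untreated arrays. On the p53-Dnmt1-null array at 24 h of TSA, the 18S ribosomal RNA control probe sets at the 3' end and the 5' end read 2549.1 and 2039.0. The untreated p53-Dnmt1-null array gave 688.1 and 223.7, the untreated p53-null array 194.0 and 88.2, and the highest of the other arrays 1292.1 and 601.5. On the array after TSA removal, the B2 repeat control read 8689.9 against 5797.3 untreated and 3925.6 in untreated p53-null cells, and the transferrin receptor control at its 3' end 140.7 against 62.8 and 16.0.

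Among the 10 largest increases and 5 largest decreases with TSA in each genotype, 3 genes lay on opposite sides of their untreated values in the genotypes at both times. The difference of the responses was 4.43 ± 0.59 for Tex101 (limma adjusted p = 0.761), -2.06 ± 0.49 for Hp (limma adjusted p = 0.994) and 3.32 ± 1.06 for U90926 (limma adjusted p = 0.994). None of these passed the adjustment. In p53-null cells the signals were near the floor for Tex101 and Hp. List members outside these were not screened, and Plk2 and Myl9, whose responses differed by 1.66 ± 0.58 and 1.58 ± 0.33 (limma adjusted p = 0.994 for both), also lay on opposite sides.

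The genotypes differed in 3643 features over 0, 24 and 48 h. Of the 10 splits of these 6 arrays into equal groups, 1 gave as many calls, the real split, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05. The other splits mix the genotypes, so the genotype difference counts as error in them and their 0 decides nothing. High epithelial genes with low matrix genes could come from a minority of epithelial cells in the p53-Dnmt1-null culture, but such cells would leave matrix genes largely in place, and the matrix median was -1.60 (95% bootstrap interval over 41 genes -2.28 to -1.12). Different starting cells stay open: 4 of 6 Y-linked probe sets were higher on every p53-Dnmt1-null array than on every p53-null array, which 8.67% of dim probe sets and 12.6% of all probe sets were, although all 6 were dim. Loss of Dnmt1 was not tested separately from the culture, so it stays open as well.

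After TSA removal 905 features were lower and 438 higher than untreated, a ratio of 2.07. A lower background on that array may account for it, since among the 1878 dimmest features 350 were lower and 74 higher and the dim bioB spike-in read 85.9 against 187.9 (the bright cre spike-in 4424.4 against 5555.5), but the test did not settle this, because its outcome depended on how bright features were selected. Selected on the mean of the pair of arrays compared, the ratio was 1.13 (223 lower, 198 higher), near balance; selected on the untreated array it was 3.19 (316 and 99), and on the TSA arrays 3.67 (330 and 90). The balanced selection was the last computed and was chosen after the other ratios were seen; those select on arrays other than the after-removal array, which favours features lower on it. Quantile normalization left 751 lower and 502 higher, between what scaling or a real shift would need. Scaling, a lasting effect of TSA and time in culture cannot be told apart here. The labels name no untreated array kept for the same 2 weeks.

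More features differed at 24 h than at 48 h of TSA in p53-Dnmt1-null cells, 1044 against 369, on the array with the high 18S signals. An artefact of that array alone would leave its 24 h to 48 h change unrelated to that in p53-null cells, which share no array with it. Across 9390 features the changes correlated at Pearson r = 0.245 (95% bootstrap interval 0.222 to 0.269) and Spearman rho = 0.279. This argues against that array as the whole source of the 24 h to 48 h change. It does not bear on the larger count at 24 h, since it does not compare counts. In p53-null cells fewer features differed at 24 h than at 48 h, 491 against 743. A batch shared by the 24 h arrays of both genotypes, or a response that differs in time, stays open and was not tested.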

How the results depend on the processing

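The tests of TSA averaged over genotypes and the selection on untreated signal were chosen after the data were seen. Of the alternative values of counts and shares, 135 stayed within 1.5 times or within the interval of the value reported and 49 did not. Many of the 135 could hardly have moved. They were limma counts of 0 in tests that recover few changes, or values as deposited. Of the named genes' alternative values 458 kept their call, 2 gained and 3 lost it, and of the lists' 352 kept, 7 gained and 9 lost it. Genotype calls were lost for the liver list with quantile normalization, the offset at the median and the mean over probe sets (percentiles 96.4, 96.0 and 95.2), the placental list with the mean over probe sets (97.1) and genes known to go up with such inhibitors with the offset at the median (3.00). The mean over probe sets also ended the calls of cholesterol genes with TSA in p53-Dnmt1-null cells (3.90) and antigen presentation after removal (25.1), and the offset at the 10th percentile those of cell cycle and mesothelial genes after removal. Size-rule counts depended on the offset and the filter, which bear on dim features by construction, and on the threshold, since 3-fold leaves out smaller changes; for the limma calls the cause was not tested. Leaving the deposited scaling as it was moved no count by more than 4 features (1002 in place of 998), and it tests little, since the arrays already shared their trimmed mean.

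With the offset at the median, higher counts were 507 for genotype, 45 for TSA in p53-null cells, 66 in p53-Dnmt1-null cells and 209 after removal, and lower counts 41, 9 and 314 for the last 3. With the offset at the 10th percentile, TSA gave 233 higher in p53-null cells and 63 lower in p53-Dnmt1-null cells, and 21.5% of induced features stayed higher after removal. With the filter at the 75th percentile, higher counts were 557, 76, 108 and 291, and lower counts 19 for TSA in p53-Dnmt1-null cells and 441 after removal. With no filter, 61 were lower with TSA in p53-Dnmt1-null cells and 1365 after removal. With a 3-fold threshold, higher and lower counts were 401 and 490, 22 and 6, 39 and 5, and 71 and 187. The overlap of Dnmt1 loss and TSA was 5 at that threshold. At 2-fold without a shared array it was 85, from larger sets, with genotype at 48 h of TSA and TSA at 24 h alone. At 24 h alone, TSA gave 317 and 174 in p53-null and 565 and 479 in p53-Dnmt1-null cells, and at 48 h alone 445 and 298, and 275 and 94. Among features with an untreated signal above the 75th percentile, 99 were higher and 316 lower after removal. For features chosen in p53-null cells the share at least 2-fold above untreated after removal was 9.66%. Most of these had not met the size rule with TSA in p53-Dnmt1-null cells.

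Without the 48 h pair the genotype test called 1112 higher and 1134 lower, 2194 of them shared with the 3643. In p53-Dnmt1-null cells limma called 1 higher feature with TSA, Tex101, with the offset at the median or no intensity trend. After removal, 0 were higher with no filter, with the mean over probe sets or with no intensity trend, where Malat1 had adjusted p of 0.195, 0.131 and 0.073. TSA averaged over genotypes gave 1 higher with the offset at the median and 0 with no filter or no intensity trend. Signals below the pooled median of 45.6 limit what can be said of silent genes.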

Other observations

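All tests and lists in this part were chosen after the genotype differences were seen. Some genes of mesothelium, the epithelial lining of body cavities, were among those higher in p53-Dnmt1-null cells. Of 10 measured mesothelial genes, 10 were higher by limma in p53-Dnmt1-null cells, with a median of 5.00. The filter left out Calb2, another mesothelial marker, whose untreated signals were 7.6 in p53-Dnmt1-null and 8.1 in p53-null cells. The transcription factor Wt1 had untreated signals of 526.7 and 0.9, and Aldh1a2, which makes retinoic acid, 287.7 and 0.6. Gpm6a, Msln, Upk3b and Podxl in that list had helped to prompt it, and Krt19 is also among the epithelial markers. After TSA removal the list's median was -0.64, with all 10 members below the untreated value, and Wt1 was still at 427.6.

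Repeat elements on the control probe sets were read at all 3 times and not tested. B1 repeat signal in p53-Dnmt1-null cells stood at -0.63 ± 0.12 (SD, n = 3 times) on the log2 scale against p53-null cells, and B2 repeat signal at 0.53 ± 0.05. With TSA, Malat1 had signals of 545.6 and 650.1 in p53-null cells against 135.8 untreated, and 121.2 and 145.3 in p53-Dnmt1-null cells against 54.4. Uhrf1 had signals of 84.1 and 44.1 with TSA in p53-null cells against 290.6 untreated.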
